A study of Homo sapiens with 16 samples.

How the data were processed

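RNA was measured by sequencing in 16 libraries of 2 human neuroblastoma cell lines with amplified MYCN, Kelly and LAN-1. Per the labels, GSK126, an inhibitor of the histone methyltransferase EZH2, was given at 2 uM for 2 or 5 days, with DMSO as the control and 2 replicates of each condition. The 2 lines, 2 treatments and 2 days gave 8 groups of 2 libraries. The deposited table held whole-read counts for 25728 gene symbols, with no normalization, and 1 column per library. Per the submitters' processing notes, FastQC, TopHat2 and featureCounts were used with GRCh37 (hg19), with no versions stated. The strand setting, the annotation and the handling of reads that fit several genes were not given in the sources used here. The labels do not say that duplicates came from separate cultures, so every p-value measures only the spread between these samples.

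Library totals ran from 912095 to 1666190 counts, with a median of 1394475.5. A gene with 0 counts in a library of the smallest total could have had up to 3 counts. Intervals and floors cover counting error only, because the libraries carried no molecular identifiers. The table held 6598 symbols with no read in any library. It held 28 symbols turned into dates, 2 of which stood for more than 1 gene, and these were kept as they stood and never named. No symbol of a mitochondrially encoded gene was present, so that share of the counts, chosen in advance as a sign of RNA quality, could not be computed.

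Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr at a minimum count of 10 on the 8 groups, which left 11863. Libraries were scaled by TMM, with factors from 0.9774 to 1.026. A robust quasi-likelihood model with 1 mean per group left 8 residual degrees of freedom, and the common biological coefficient of variation was 5.31%. P-values were adjusted over all 11863 genes by Benjamini-Hochberg, and a gene was called where the adjusted p was under 0.05. Unless another tool is named, each adjusted p for a gene comes from edgeR. Levels are given in CPM, the count divided by the TMM-scaled library total and expressed per 1e6 counts, as mean ± SD of 2 libraries, and log2 fold changes as estimate ± SE from the model with n = 2 per group. The fitted change of a gene with almost no counts in 1 group depends on the prior count. Where a group had 0 counts, the text therefore gives the fold against a floor of 3 counts over that group, worded as at least that fold. The count of the other group was taken as exact, so the true fold can be smaller where that count is low. Where a group had 1 to 3 counts, the ratio is given with its exact 95% counting interval. No fold is given where both groups held 3 counts or fewer.

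The comparisons and tests were chosen before the data were examined. They were GSK126 against DMSO within each line and day, the mean of these 4 differences, the difference of the GSK126 effect between lines and between days, and day 5 against day 2 in DMSO. Overlaps of calls were compared with the number that independent lists would share, by a one-sided Fisher's exact test across genes, which are not independent replicates. Named genes followed a rule fixed in advance. It took fixed genes in every main comparison, among them EZH2, EZH1, MYCN, CASZ1, CLU, NGFR, RUNX3 and CDKN1A, and results for a few genes are not reported here. It added the largest called changes with a mean of at least 2 CPM in some group. Between 2 groups, a largest change was taken only where the libraries of the groups did not overlap in CPM. The largest changes named are therefore not the largest of all called genes. Added as well were up to 4 members of each gene list with the smallest adjusted p at day 5. Symbols of unnamed loci, XIST, TSIX and genes of the Y chromosome were passed over. The position of named genes on GRCh37 came from GENCODE 44 lifted to that build. Of the symbols, 21873 matched directly and 1436 through a synonym, and 2419 had no match.

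In all, 31 gene lists were fixed in advance. They covered PRC2 subunits, PRC1 subunits, HOX genes, developmental transcription factors bound by PRC2, EZH2-repressed genes reported in neuroblastoma, neuronal differentiation, adrenergic identity, mesenchymal identity, Schwann cell and glial markers, haematopoietic markers, epithelial markers and endothelial markers. They also covered CDK inhibitors, G1/S and DNA replication, mitosis, MYC targets, the MYCN amplicon, p53 targets, cell death regulators, antigen presentation, interferon-stimulated genes, sterol synthesis and uptake, the integrated stress and unfolded protein response, hypoxia and glycolysis, germline genes, immediate early genes, retinoid response, imprinted genes, H3K27 and H3K36 modifiers, the let-7 and LIN28B axis, and heat shock. Each list with at least 3 tested genes was compared with all other tested genes by camera in limma 3.58.1, at a preset correlation between genes of 0.01, and adjusted over 224 tests (28 lists in 8 contrasts). Of these tests, 76 were called, and 9 were called when the correlation was estimated from the list itself. Whichever library was left out, 34 of the 76 calls were kept at the preset correlation, all 9 among them. The median of a list sets genes without reads in 1 group to the bound described above and leaves out genes near the floor in both. The haematopoietic list had 2 tested genes, the endothelial list 2 and the epithelial list 0, and these 3 lists were not tested.

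Alternatives fixed before the data were examined were DESeq2 1.42.0, limma-voom, size factors of DESeq2 in edgeR, no filter, libraries thinned to the smallest total, a replicate term, fits on the line or the contrast alone, each library left out in turn, an adjusted p under 0.01 and glmTreat against a log2 change of 0.5. The estimated correlation and the fry rotation test were the alternatives for lists. A correction for GC content and transcript length, available for 98.36% of tested genes, was added after the data were seen. The same holds for a fit without the 2 libraries that stood apart, for leaving out libraries in the composition and overlap results, and for the share of RMRP and RPPH1. No test of outlying libraries was run, as each group held only 2.

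The pipeline was tested on simulated counts of 11689 genes. In Kelly with GSK126 at day 5, 200 of them were changed and 27 others were shifted together as a list. It called 14 of 67 genes changed by a log2 of 0.5, 50 of 67 changed by 1 and 62 of 66 changed by 2. Of 149 calls, 15 were members of the shifted list and 8 (5.37%) were unchanged genes. Levels were the mean of each line, and the changed genes were drawn from those at 5 CPM or more in Kelly. No GC trend and no library that stood apart was simulated. These rates therefore do not cover such libraries or changes of genes with almost no counts. Tables and figures were made in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.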

Results

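The series measured gene expression in Kelly and LAN-1, 2 neuroblastoma lines with amplified MYCN, after 2 or 5 days of the EZH2 inhibitor GSK126 or DMSO. EZH2 is the catalytic subunit of PRC2, the complex that places the repressive mark H3K27me3. Each of the 8 groups held 2 libraries. Totals per library ran from 1102922 to 1666190 counts in Kelly and from 912095 to 1597429 in LAN-1. The first principal component separated the lines and held 81.94% of the variance, and the second held 3.651%. Within pairs of duplicates the variance was 1.11 to 2.04 times that of counting alone, highest for LAN-1 with GSK126 at day 5 (2.04) and for Kelly with DMSO at day 2 (1.81). These 2 pairs also differed most along the GC content of genes, with correlations of 0.517 and 0.480 across genes. Genes are not independent replicates in any correlation given here.

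In Kelly at day 5, GSK126 turned on genes that had no read in the DMSO libraries of that day, raised collagens and HLA class I genes, and lowered the enzymes of noradrenaline synthesis. YBX3, a Y-box nucleic acid binding protein, went from 0 to 24.1 ± 0.646 CPM, at least 24.6-fold (edgeR adjusted p = 8.44e-14, n = 2 per group). INSR, the insulin receptor, went from 0 to 18.3 ± 4.27 CPM, at least 18.5-fold (adjusted p = 5.51e-11). The Notch receptor gene NOTCH2 rose 54.8-fold (95% interval 18.4 to 268.9, adjusted p = 1.73e-21), and CCND2, which encodes the G1 cyclin D2, rose 84.6-fold (14.7 to 3388, adjusted p = 2.29e-11). DBH, the enzyme that makes noradrenaline from dopamine, fell from 824 ± 4.26 to 332 ± 28.3 CPM (log2 fold change -1.31 ± 0.09, adjusted p = 2.67e-23).

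The bounds were also at least 8.46-fold for SNX10, a sorting nexin, and 6.85-fold for COTL1, an actin-binding protein. They were 6.04-fold for CD97, an adhesion receptor, and 5.64-fold each for KIAA1804 and FNDC4. Among genes with smaller folds, COL1A1, a chain of type I collagen, rose from 24.98 ± 6.95 to 120.8 ± 6.59 CPM (2.29 ± 0.19, adjusted p = 3.84e-19). On GRCh37, YBX3 lies at chromosome 12:10851688-10875922, INSR at 19:7112266-7294425, NOTCH2 at 1:120454176-120643366, COL1A1 at 17:48261462-48278993 and DBH at 9:136501485-136524451. Among the genes taken by the naming rule, SH2B2 fell most by fold (ratio 0.105, 0.0120 to 0.425, adjusted p = 0.0141). IGF2, an imprinted growth factor gene, fell (-1.42 ± 0.11, adjusted p = 8.62e-19). RRP7B (-1.59 ± 0.42), ENTHD2 (-1.44 ± 0.45), KLF15 (-1.43 ± 0.36), PSMC3IP (-1.36 ± 0.35) and SLC2A4RG (-1.32 ± 0.34) also fell, with adjusted p between 0.00607 and 0.0367. In all, 581 genes were called, 391 higher and 190 lower. DESeq2 called 151. Leaving out 1 library left 355 calls without DMSO replicate 1, 239 without DMSO replicate 2, 304 without GSK126 replicate 1 and 280 without GSK126 replicate 2.

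Of the 71 named genes called in Kelly at day 5, 36 kept their call whichever library was left out. Among the largest changes, CD97, FNDC4, SH2B2, RRP7B, ENTHD2, KLF15, PSMC3IP and SLC2A4RG did not. Their highest adjusted p was 0.0727 (CD97, without GSK126 replicate 2), 0.0549 (FNDC4, without DMSO replicate 2), 0.285 (SH2B2, without DMSO replicate 2) and 0.258 (RRP7B, without GSK126 replicate 1). It was 0.278 for ENTHD2 and 0.469 for PSMC3IP without DMSO replicate 2, and 0.0801 for KLF15 and 0.475 for SLC2A4RG without GSK126 replicate 2.

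The mesenchymal identity list moved up in Kelly at day 5, with 9 of 24 tested members higher and 0 lower over all genes, and 12 higher adjusted over the list alone (median log2 0.81, limma camera adjusted p = 1.00e-17, and 0.0113 with an estimated correlation). COL3A1, a chain of type III collagen (2.81 ± 0.30, adjusted p = 9.99e-13), and FN1, the matrix protein fibronectin (0.91 ± 0.11, adjusted p = 6.12e-10), rose with COL1A1 and NOTCH2. KDR, a receptor gene on the list of endothelial markers, was also higher in Kelly at day 5 (1.52 ± 2.15 CPM in DMSO and 11.2 ± 5.03 CPM with GSK126, 2.66 ± 0.68, edgeR adjusted p = 0.00673), but not without DMSO replicate 1 or GSK126 replicate 1 (up to 0.240). The adrenergic identity list moved down, with 8 of 26 members lower and 3 higher over all genes, and 10 lower and 3 higher adjusted over the list alone (median -0.23, camera adjusted p = 3.98e-13, and 0.0168 with an estimated correlation). TH, the rate-limiting enzyme of catecholamine synthesis (-1.04 ± 0.12, adjusted p = 8.26e-12), and DDC, which makes dopamine (-0.95 ± 0.11, adjusted p = 1.09e-10), fell with DBH. INSM2, a zinc finger factor, also fell (-0.84 ± 0.10, adjusted p = 1.68e-10).

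MYC targets moved down in Kelly at day 5 with 6 of 44 members lower and 0 higher over all genes, and 12 lower adjusted over the list alone (median -0.23, camera adjusted p = 8.17e-09, and 0.0336 with an estimated correlation). NOLC1, a nucleolar protein gene, fell (-0.38 ± 0.09, adjusted p = 0.00441), but not without DMSO replicate 2 (0.0873) or GSK126 replicate 2 (0.132). MYCN itself fell from 2508 ± 153.8 to 1915 ± 20.1 CPM (-0.39 ± 0.08, adjusted p = 1.81e-04). The antigen presentation list moved up with 2 of 11 members higher, and 3 adjusted over the list alone (median 0.33, camera adjusted p = 1.19e-04, and 0.0426 with an estimated correlation). HLA-B (3.63 ± 0.45, adjusted p = 2.81e-10) and HLA-C (1.66 ± 0.25, adjusted p = 1.51e-07), which encode HLA class I chains, rose. These 2 genes share sequence, so reads may have been divided between them.

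Further lists were called by camera in Kelly at day 5 but not with an estimated correlation. The G1/S list moved down, 10 of 40 members lower over all genes and 10 adjusted over the list alone (camera adjusted p = 3.60e-07, and 0.111 with an estimated correlation), among them the replicative helicase subunit MCM5 (-0.64 ± 0.11, adjusted p = 8.40e-06). Hypoxia and glycolysis moved down, 6 of 28 lower over all genes, and 10 lower with 1 higher adjusted over the list alone (median -0.30, 8.29e-06, and adjusted p = 0.127 with an estimated correlation). The hexokinase HK2 (-0.89 ± 0.14, adjusted p = 4.52e-07) and the aldolase ALDOA (-0.43 ± 0.09, adjusted p = 2.27e-04) fell. The integrated stress list moved down, 6 of 28 lower and 7 adjusted over the list alone (3.35e-04, and adjusted p = 0.121 with an estimated correlation), with the amino acid transporter SLC7A5 lower (-0.83 ± 0.11, adjusted p = 1.50e-09). Mitosis moved down, 2 of 36 lower and 4 adjusted over the list alone (3.52e-04, and adjusted p = 0.164 with an estimated correlation). The retinoid list moved up, 2 of 8 higher and 3 adjusted over the list alone (8.99e-05, and adjusted p = 0.107 with an estimated correlation), through CRABP2, which binds retinoic acid (1.81 ± 0.26, adjusted p = 6.36e-08), and the receptor tyrosine kinase RET (1.25 ± 0.12, adjusted p = 1.24e-14).

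The list of developmental transcription factors bound by PRC2 moved up in Kelly at day 5, with 4 of 32 members higher and 1 lower, and 6 higher and 1 lower adjusted over the list alone (median 0.38, camera adjusted p = 0.0386, and 0.279 with an estimated correlation). This call was lost without any 1 of 14 of the 16 libraries, with a camera adjusted p up to 0.149 without GSK126 day 5 replicate 1. MSX2 (2.44 ± 0.44, adjusted p = 1.93e-05) and FOXC1 (1.49 ± 0.26, adjusted p = 7.61e-06), both homeobox or forkhead factors, rose, and TFAP2B, a neural crest factor, fell (-0.65 ± 0.11, adjusted p = 1.74e-06). Of the 5 EZH2-repressed genes reported in neuroblastoma, 2 were higher, and 3 adjusted over the list alone (camera adjusted p = 0.0372, and 0.279 with an estimated correlation), but the call was lost without 2 libraries (up to 0.179 without GSK126 day 5 replicate 1). NGFR, the low-affinity neurotrophin receptor, rose (1.65 ± 0.42, adjusted p = 0.00689), but not without DMSO replicate 2 (0.218) or GSK126 replicate 1 (0.115).

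The p53 target list moved up in Kelly at day 5 (2 of 27 higher, and 2 adjusted over the list alone, camera adjusted p = 0.0254, and 0.128 with an estimated correlation), with the kinase PLK2 higher (1.504 ± 0.13, adjusted p = 2.78e-18). Interferon-stimulated genes moved up (2 of 14 higher, and 2 adjusted over the list alone, 0.0463, and adjusted p = 0.164 with an estimated correlation). PRC2 subunits moved down with no member called over all genes or adjusted over the list alone (0.0372, and adjusted p = 0.161 with an estimated correlation). The MYCN amplicon moved down, with MYCN the only member called, 1 of 5 in both adjustments (0.0419, and adjusted p = 0.221 with an estimated correlation). Heat shock genes moved down with no member called (0.0232, and adjusted p = 0.334 with an estimated correlation). The camera call of interferon-stimulated genes was lost without any 1 of 11 of the 16 libraries (up to 0.164 without DMSO day 5 replicate 2). Calls were also lost without 3 libraries for PRC2 subunits (up to 0.0660 without DMSO day 5 replicate 1) and the MYCN amplicon (0.231 without GSK126 day 5 replicate 1), and without 1 for p53 targets (0.0527, DMSO day 5 replicate 1) and heat shock genes (0.0878, DMSO day 5 replicate 2). Of the genes named in every comparison, EZH2 (-0.28 ± 0.11, adjusted p = 0.149), EZH1 (-0.10 ± 0.18, 0.860), CASZ1 (-0.05 ± 0.15, 0.932), CLU (0.41 ± 0.18, 0.204), RUNX3 (-0.02 ± 0.33, 0.995) and CDKN1A (0.33 ± 0.16, 0.277) did not pass the test.

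Neuronal differentiation genes changed in both directions in Kelly at day 5, and that list did not pass (camera adjusted p = 0.520). CHGA, the granule protein chromogranin A (-0.57 ± 0.08, adjusted p = 6.45e-09), the neuropeptide gene GAL (-1.08 ± 0.17, 3.95e-07) and the adhesion molecule gene CNTNAP2 (-0.50 ± 0.09, 7.61e-06) fell while RET rose. Imprinted genes likewise split (0.579), with DLK1, a Notch family ligand, lower (-1.02 ± 0.08, adjusted p = 1.27e-19) and NDN, a regulator of neuronal growth, higher (2.47 ± 0.42, 1.09e-05). PEG3, a zinc finger gene, was higher (0.94 ± 0.20, 4.73e-04). SPRY4, an inhibitor of receptor kinase signalling, rose (1.44 ± 0.26, 2.50e-05) without a call for the immediate early list (0.141). The sterol list did not pass in Kelly at day 5 (0.253).

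**Figure D1:**
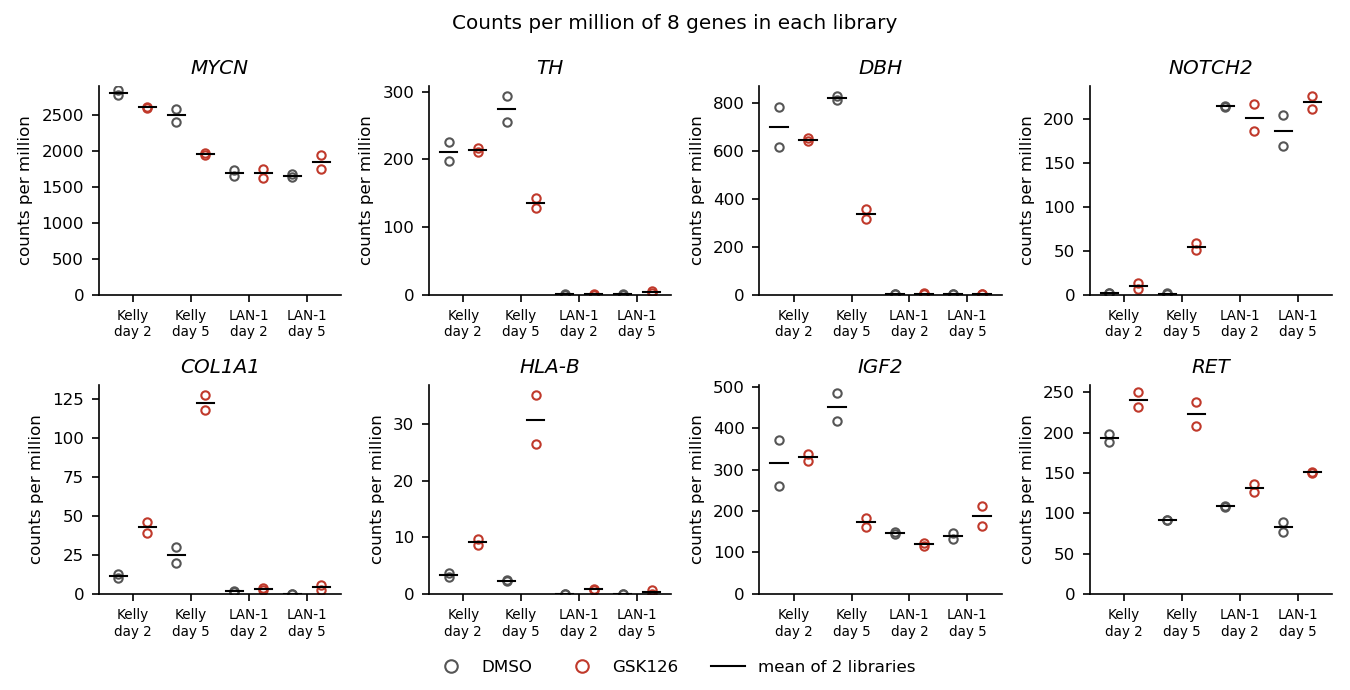
Levels of named genes in each library, in CPM without TMM scaling, by line, treatment and day. Points are libraries and bars are the mean of 2 libraries. In Kelly at day 5, DBH stood at 829.1 and 810.8 CPM with DMSO and at 358.2 and 317.3 CPM with GSK126.

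In LAN-1 at day 5, GSK126 raised RET and the cholesterol synthesis enzymes DHCR7 and LSS and lowered PDK1. RET rose from 84.4 ± 7.67 to 152.4 ± 2.07 CPM (0.85 ± 0.14, adjusted p = 5.89e-06, n = 2 per group). DHCR7, the last enzyme of cholesterol synthesis, rose from 127.7 to 222.5 CPM (0.79 ± 0.13, adjusted p = 7.44e-06), and LSS, which closes the sterol rings, rose (0.58 ± 0.09, 5.89e-06). PDK1, a kinase that restrains pyruvate dehydrogenase, fell from 193.4 ± 5.70 to 113.6 ± 1.40 CPM (-0.77 ± 0.13, 1.94e-05).

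In all, 434 genes were called in LAN-1 at day 5, 291 higher and 143 lower, and DESeq2 called 149. GSK126 replicate 2, the smallest library, stood apart from replicate 1 along GC content. Without it 153 genes were called (133 higher, 20 lower), and without replicate 1 735 were (373 higher, 362 lower). The count was 139 without DMSO replicate 1 and 145 without DMSO replicate 2. Of 57 named genes called, 9 kept their call in each of these fits. Among them were PDK1, RET, DHCR7, LSS, KMT2D, CREBBP, KCNQ1OT1 and TBX20. On GRCh37, RET lies at chromosome 10:43572512-43625799 and DHCR7 at 11:71139239-71163914.

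Other large rises in LAN-1 at day 5 rested on few counts. CRABP2 rose 19.2-fold (3.01 to 803.6, adjusted p = 0.00296), but its call was lost without DMSO replicate 2 (0.0837). CDKN1A, the CDK inhibitor p21, rose 11.9-fold (2.90 to 104.5, 0.00179), but not without DMSO replicate 2 (0.0851). The potassium channel genes KCNC4 (18.1-fold, 2.81 to 758.9) and KCNH3 (17.0-fold, 2.61 to 714.2) and STARD8 (14.7-fold, 2.21 to 624.9) rose. SOX13 and COL1A1 were at least 3.39-fold higher and ARHGAP31 at least 3.02-fold. These 6 calls were lost without some library, with a highest adjusted p of 0.182 (KCNC4), 0.276 (KCNH3), 0.284 (SOX13) and 0.196 (COL1A1) without DMSO replicate 1. It was 0.414 for STARD8 without GSK126 replicate 2 and 0.379 for ARHGAP31 without GSK126 replicate 1.

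The largest falls among named genes in LAN-1 at day 5 were smaller. EPHA7, an ephrin receptor, fell (-0.91 ± 0.20, adjusted p = 0.00167), but not without DMSO replicate 1 (0.110). COQ3 (-1.60 ± 0.47), SLC17A8 (-1.33 ± 0.35), CCDC82 (-1.06 ± 0.30), EMC2 (-1.03 ± 0.29), KIAA1841 (-1.01 ± 0.29), SCARNA7 (-0.96 ± 0.28) and GPRC5B (-0.94 ± 0.27) fell, with adjusted p from 0.0141 to 0.0409. Each of these 7 lost its call without 3 or 4 of the 4 libraries. The highest adjusted p was 0.193 (COQ3) and 0.162 (GPRC5B) without GSK126 replicate 1, and 0.273 (SLC17A8), 0.320 (KIAA1841) and 0.572 (SCARNA7) without GSK126 replicate 2. It was 0.488 for CCDC82 without DMSO replicate 1 and 0.184 for EMC2 without DMSO replicate 2.

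The neuronal differentiation list moved up in LAN-1 at day 5, with 9 of 48 members higher and 0 lower, and 15 higher adjusted over the list alone (median 0.33, camera adjusted p = 2.61e-06, and 0.0168 with an estimated correlation). Beside RET, the microtubule protein gene MAP1B (0.40 ± 0.08, adjusted p = 5.23e-04), CHGA (0.44 ± 0.10, 0.00329) and the adhesion molecule gene L1CAM (0.75 ± 0.17, 0.00353) rose. Their highest adjusted p was 0.119 (MAP1B, without DMSO replicate 2), 0.0961 (CHGA, without DMSO replicate 1) and 0.179 (L1CAM, without GSK126 replicate 2). The sterol list moved up with 9 of 27 members higher, and 15 adjusted over the list alone (median 0.31, camera adjusted p = 3.05e-13, and 0.0770 with an estimated correlation). MVD, an enzyme of the pathway, rose (0.90 ± 0.18, adjusted p = 4.82e-04), but not without DMSO replicate 1 (0.115) or GSK126 replicate 2 (0.247).

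Developmental factors bound by PRC2 moved up in LAN-1 at day 5, with 5 of 32 higher and 9 adjusted over the list alone (median 0.56, camera adjusted p = 2.54e-04, and 0.107 with an estimated correlation). TBX20 (0.74 ± 0.16, adjusted p = 8.74e-04), HAND1 (0.70 ± 0.13, 1.62e-04), BARX1 (1.696 ± 0.37, 0.00169) and EN1 (11.7-fold, 3.65 to 59.7, 8.74e-04), all developmental transcription factors, rose. HAND1 (0.0894) and BARX1 (0.0843) lost their call without DMSO replicate 1, and EN1 without DMSO replicate 2 (0.0764). The retinoid list moved up, 2 of 8 higher and 4 adjusted over the list alone (3.71e-04, and adjusted p = 0.107 with an estimated correlation). Of the EZH2-repressed genes 1 of 5 was higher, and 3 adjusted over the list alone (0.0193, and adjusted p = 0.221 with an estimated correlation). That gene was CLU, a secreted chaperone (0.48 ± 0.13, adjusted p = 0.0136), which lost its call without DMSO replicate 1 (0.192), DMSO replicate 2 (0.0858) or GSK126 replicate 2 (0.242).

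The list of H3K27 and H3K36 modifiers passed as higher in LAN-1 at day 5 with 5 of 15 members higher, and 6 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.0281, and 0.255 with an estimated correlation). Its median was -0.01 and its mean 0.10, so they differed in sign. KMT2D, an H3K4 methyltransferase (0.76 ± 0.11, adjusted p = 4.26e-07), and CREBBP, an acetyltransferase of H3K27 (0.52 ± 0.09, 7.06e-05), rose. KDM6B, an H3K27 demethylase, rose (0.55 ± 0.12, 0.00159), but not without DMSO replicate 1 (0.174) or GSK126 replicate 2 (0.0751). KCNQ1OT1, an imprinted antisense RNA, was higher (1.31 ± 0.20, adjusted p = 5.27e-07), while the imprinted list did not pass (0.0916). As the strand setting was not given, reads of the overlapping KCNQ1 may be among its counts. KMT2D, CREBBP and KCNQ1OT1 were not called after the correction for GC content and length.

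Mitosis genes moved down in LAN-1 at day 5 with 1 of 36 higher and 1 lower, and 1 higher and 5 lower adjusted over the list alone (camera adjusted p = 2.25e-04, and 0.158 with an estimated correlation). MKI67, a marker of proliferating cells, was higher (0.46 ± 0.09, adjusted p = 1.35e-04), but not without DMSO replicate 2 (0.0573). MYC targets moved down, 3 of 44 lower and 5 adjusted over the list alone (0.00148, and adjusted p = 0.127 with an estimated correlation). Mesenchymal genes moved up, 2 of 24 higher, and 6 higher and 1 lower adjusted over the list alone (0.00754, and adjusted p = 0.158 with an estimated correlation). Schwann cell and glial markers moved up through L1CAM, 1 of 4 and 2 adjusted over the list alone (0.0306, and adjusted p = 0.161 with an estimated correlation). Immediate early genes moved up, 1 of 16 in both adjustments (0.0461, and adjusted p = 0.162 with an estimated correlation). Heat shock genes passed as lower, with 1 of 12 higher and 1 lower, and 1 higher and 5 lower adjusted over the list alone (0.0371, and adjusted p = 0.376 with an estimated correlation), with a median of -0.21 but a mean of 0.14. Of the lists called by camera in LAN-1 at day 5, some lost their call when 1 of the 16 libraries was left out. These were immediate early genes (10 libraries, up to 0.187) and heat shock genes (6, up to 0.225), both highest without GSK126 day 5 replicate 2, the modifiers of H3K27 and H3K36 (2, up to 0.153 without DMSO day 5 replicate 2) and Schwann cell markers (2, up to 0.140 without DMSO day 5 replicate 1). EZH2-repressed genes lost it without GSK126 day 5 replicate 2 (0.107) and mesenchymal genes without GSK126 day 5 replicate 1 (0.0874).

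Of the genes named in every comparison, EZH2 (-0.31 ± 0.14, adjusted p = 0.211), EZH1 (-0.83 ± 0.30, 0.107), MYCN (0.14 ± 0.08, 0.362), CASZ1 (0.68 ± 0.25, 0.104) and NGFR (1.60 ± 0.58, 0.106) did not pass in LAN-1 at day 5. RUNX3 had 0 counts in both groups. Within the amplified region, DDX1, a helicase gene, was lower (-0.25 ± 0.08, adjusted p = 0.0416), but its call was lost without 3 of the 4 libraries, up to 0.491 without GSK126 replicate 2. PFKP, a glycolytic enzyme, was higher (1.18 ± 0.30, 0.00750), but not without DMSO replicate 1 (0.241) or GSK126 replicate 2. No list call was made at day 5 in either line for PRC1 (Kelly 0.9004, LAN-1 0.939), HOX genes (0.920, 0.470), CDK inhibitors (0.975, 0.965), cell death (0.930, 0.886), germline genes (0.474, 0.677) or the let-7 axis (0.156, 0.141), all camera adjusted p.

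**Figure D2:**
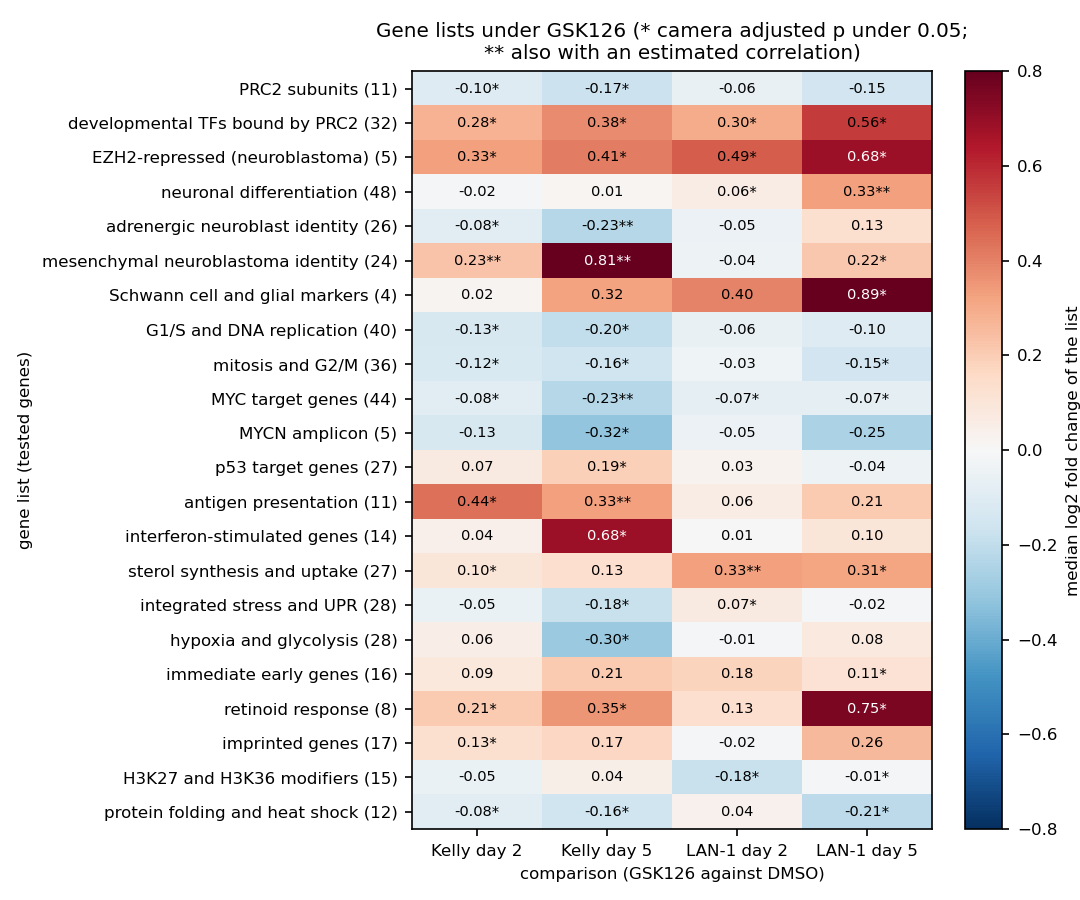
Median log2 fold change (GSK126 over DMSO) of the tested members of each gene list in the 4 single comparisons, with 1 star for a camera adjusted p under 0.05 and 2 stars where the call held with an estimated correlation. Genes with 0 counts in 1 group entered at their bound. Mesenchymal genes stood at 0.81 in Kelly at day 5 and sterol genes at 0.33 in LAN-1 at day 2.

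The lines were then compared with each other at day 5, where YBX3, INSR, SNX10 and NOTCH2 rose in Kelly and were expressed in LAN-1 in DMSO already (YBX3 at 166.1 ± 0.460 CPM, n = 2). MYCN differed between lines (LAN-1 minus Kelly, 0.53 ± 0.11, edgeR adjusted p = 0.00118), as it fell in Kelly alone. CDKN1A differed too (3.09 ± 0.79, 0.0136), but its call was lost without 2 of the 8 libraries, up to 0.213 without LAN-1 DMSO replicate 2. Neuronal differentiation moved higher in LAN-1 than in Kelly, with 4 of 48 members called with a positive difference and 0 with a negative one, and 8 and 0 adjusted over the list alone (median 0.17, camera adjusted p = 3.13e-04, and 0.0414 with an estimated correlation).

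In all, 220 genes differed between lines at day 5, 109 with a higher and 111 with a lower effect in LAN-1, and DESeq2 called 63. The count moved to 117 without Kelly DMSO replicate 2, 131 without Kelly GSK126 replicate 2, 128 without LAN-1 DMSO replicate 1, 479 without LAN-1 GSK126 replicate 1 and 142 without LAN-1 GSK126 replicate 2. Across all tested genes the correlation of the log2 changes was 0.139 (Pearson).

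The lines shared 64 genes called higher at day 5, where independent lists would share 9.59 (Fisher's exact p = 2.71e-35 across genes), among them RET, CRABP2, COL1A1, FN1 and HLA-C. RET kept its call in both lines whichever library was left out, while in LAN-1 the calls of CRABP2, COL1A1, FN1 and HLA-C did not hold in every leave-out, with FN1 lost without 2 of 4 libraries (up to 0.401) and HLA-C without 3 (up to 0.164). The 64 fell to 41 without Kelly DMSO replicate 2, 39 and 40 without Kelly GSK126 replicates 1 and 2, 28 and 30 without LAN-1 DMSO replicates 1 and 2 and 35 without LAN-1 GSK126 replicate 2. DESeq2 shared 15, thinned libraries 41 and an adjusted p under 0.01 left 28, and in each of these settings Fisher's exact p was at most 5.67e-14. The lines shared 8 genes called lower, with 2.29 for independent lists (Fisher's exact p = 0.00211), but 1 to 4, with Fisher's exact p from 0.0700 to 0.578, in 7 of the 8 leave-outs, and 12 without LAN-1 GSK126 replicate 1. With DESeq2 1 was shared (Fisher's exact p = 0.407), and after the correction for GC content and length 31. In all, 77 genes were called in both lines and 72 had the same direction.

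**Figure D3:**
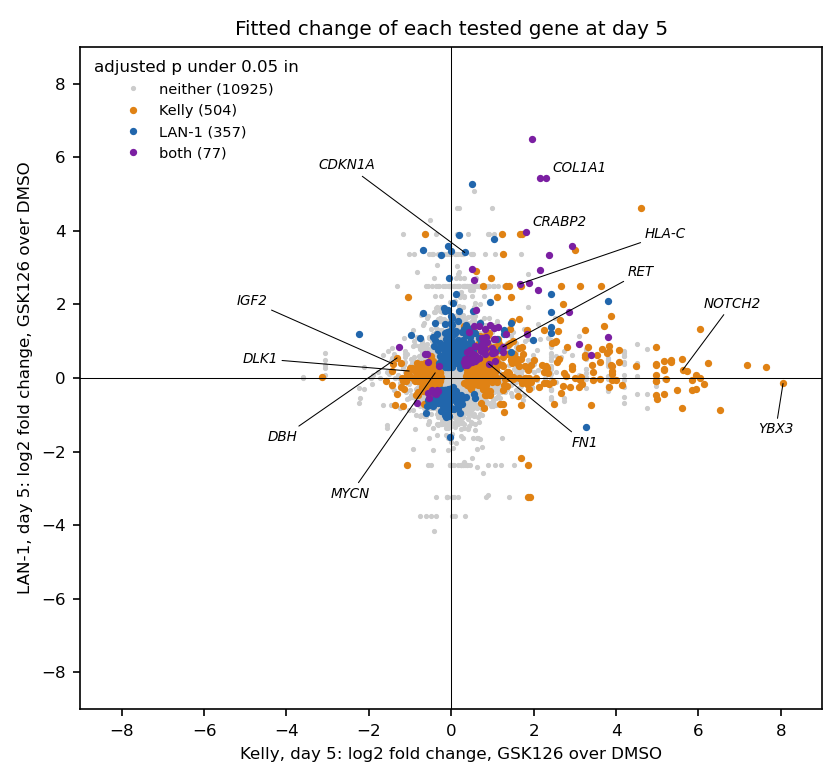
Fitted log2 fold change of each tested gene at day 5 in Kelly (horizontal) and LAN-1 (vertical), coloured by where the gene was called by edgeR. In all, 504 genes were called in Kelly alone, 357 in LAN-1 alone and 77 in both. Values far from 0 come from genes with few counts in 1 group.

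At day 2 in Kelly, GSK126 raised COL1A1 and a few other genes. COL1A1 rose from 11.4 ± 2.19 to 42.1 ± 5.40 CPM (1.84 ± 0.27, adjusted p = 4.44e-06, n = 2 per group), and AGRN, a basement membrane proteoglycan, rose from 11.5 ± 4.78 to 38.1 ± 4.19 CPM (1.65 ± 0.27, 6.81e-05). THBS1, a matrix glycoprotein, rose 19.97-fold (3.24 to 822.5, 0.0409), NOTCH2 rose (2.35 ± 0.57, 0.0483) and CNN2, an actin-binding calponin, rose (1.69 ± 0.40, 0.0409). CEP44, a centrosome protein gene, fell (-0.55 ± 0.11, 0.00862). Only COL1A1 kept its call whichever library was left out.

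The highest adjusted p in Kelly at day 2 was 0.0752 for AGRN and 0.297 for CEP44 without DMSO replicate 1, 0.402 for THBS1 and 0.707 for NOTCH2 without GSK126 replicate 2, and 0.730 for CNN2 without GSK126 replicate 1. The mesenchymal list moved up, 5 of 24 higher in both adjustments (over all genes and adjusted over the list alone, median 0.23, camera adjusted p = 1.40e-06, and 0.0336 with an estimated correlation). In all, 21 genes were called, 20 higher and 1 lower, with 2 by DESeq2. The count was 2 without DMSO replicate 1, 11 without DMSO replicate 2, 5 without GSK126 replicate 1 and 6 without GSK126 replicate 2. Of the genes named in every comparison, EZH2 (-0.13 ± 0.11, adjusted p = 0.828), EZH1 (-0.02 ± 0.17, 0.995), MYCN (-0.13 ± 0.08, 0.741), CASZ1 (0.23 ± 0.15, 0.766), CLU (-0.07 ± 0.17, 0.970), NGFR (0.76 ± 0.54, 0.796), RUNX3 (0.33 ± 0.36, 0.894) and CDKN1A (0.26 ± 0.17, 0.773) did not pass.

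Other lists were called by camera in Kelly at day 2, none with an estimated correlation. Antigen presentation moved up, 1 of 11 higher and 2 adjusted over the list alone (0.00295, and adjusted p = 0.104 with an estimated correlation). Mitosis (8.29e-06, and adjusted p = 0.121) and G1/S genes (6.81e-05, and adjusted p = 0.161 with an estimated correlation) moved down with 0 members called in either adjustment. Developmental factors moved up, 1 of 32 in both adjustments (0.0196, and adjusted p = 0.236 with an estimated correlation), as did EZH2-repressed genes, with 0 of 5 called and 1 adjusted over the list alone (0.0307, and adjusted p = 0.248). Adrenergic genes moved down with 1 of 26 higher, and 1 higher and 2 lower adjusted over the list alone (0.0187, and adjusted p = 0.221 with an estimated correlation). The remaining calls had no member called over all genes. These were sterol (0.0117, and adjusted p = 0.347), retinoid (0.0254, 0.245) and imprinted genes (0.0325, 0.221) upward, and PRC2 subunits (0.0210, 0.140), MYC targets (0.0149, 0.192) and heat shock (0.0112, 0.285) downward, each with the adjusted p with an estimated correlation given after the camera value. When 1 of the 16 libraries was left out, the camera call was lost for developmental factors in 8 cases (up to 0.192 without GSK126 day 2 replicate 2), imprinted genes in 3 (0.363), EZH2-repressed genes in 2 (0.439), PRC2 subunits in 2 (0.421), sterol genes in 2 (0.113), heat shock genes in 2 (0.104) and retinoid genes in 2 (0.0962), the last 6 highest without DMSO day 2 replicate 1. It was lost for adrenergic genes in 2 cases (0.348) and MYC targets in 1 (0.218), highest without DMSO day 2 replicate 2.

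At day 2 in LAN-1, genes of sterol synthesis were higher with GSK126. The list moved up with 7 of 27 members higher and 0 lower, and 19 higher adjusted over the list alone (median 0.33, camera adjusted p = 4.04e-31, and 0.0168 with an estimated correlation). HMGCS1 (0.56 ± 0.08, edgeR adjusted p = 1.15e-05), MSMO1 (0.64 ± 0.12, 0.00110) and IDI1 (0.59 ± 0.12, 0.00239), all enzymes of the pathway, were chosen as examples after their values were seen. LIPG, a lipase that acts on lipoproteins, rose from 11.8 ± 2.31 to 36.1 ± 19.3 CPM (1.59 ± 0.29, adjusted p = 9.10e-04, n = 2 per group). COL6A1, a chain of type VI collagen (0.92 ± 0.17, 9.10e-04), PDGFRA, a growth factor receptor (1.07 ± 0.23, 0.0108), WASF3, an actin regulator (1.14 ± 0.25, 0.0132), and PCYT2, an enzyme of phospholipid synthesis (0.82 ± 0.19, 0.0214), rose.

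None of these 5 largest calls in LAN-1 at day 2 was kept in every leave-out. The highest adjusted p was 0.981 for LIPG and 0.385 for COL6A1 without GSK126 replicate 1, 0.890 for PCYT2 without GSK126 replicate 2, and 0.531 for WASF3 and 0.400 for PDGFRA without DMSO replicate 1. In all, 18 genes were called, all higher, with 2 by DESeq2. The count was 3 without DMSO replicate 1, 5 without DMSO replicate 2, 8 without GSK126 replicate 1 and 14 without GSK126 replicate 2. Developmental factors moved up, 1 of 32 and 2 adjusted over the list alone (camera adjusted p = 0.00263, and 0.161 with an estimated correlation), and so did neuronal genes, 0 of 48 and 1 adjusted over the list alone (0.0390, and adjusted p = 0.161). H3K27 and H3K36 modifiers moved down, 0 of 15 and 1 adjusted over the list alone (1.07e-04, and adjusted p = 0.107 with an estimated correlation). EZH2-repressed genes (0 of 5 in both adjustments, 0.0169, and adjusted p = 0.221) and the stress list (0 of 28, and 1 adjusted over the list alone, 0.0336, and adjusted p = 0.255) moved up. MYC targets moved down (0 of 44 in both adjustments, 0.0108, and adjusted p = 0.166 with an estimated correlation). When 1 of the 16 libraries was left out, the camera call was lost for neuronal genes in 8 cases (up to 0.207 without DMSO day 2 replicate 2), the stress list in 3 (0.324) and MYC targets in 2 (0.159), both highest without GSK126 day 2 replicate 1, and EZH2-repressed genes in 1 (without DMSO day 2 replicate 1).

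Of the genes named in every comparison, EZH2 (-0.33 ± 0.13, adjusted p = 0.627), EZH1 (-0.10 ± 0.29, 0.994), MYCN (-0.02 ± 0.08, 1), CASZ1 (0.49 ± 0.22, 0.755), CLU (0.12 ± 0.12, 0.939) and NGFR (1.25 ± 0.56, 0.755) did not pass in LAN-1 at day 2. CDKN1A went from 0 to 5 counts and did not pass (edgeR adjusted p = 0.499). Its fold against the floor was 2.03 with the 5 counts taken as exact. RUNX3 had 0 counts in both groups. Between the lines at day 2, AGRN alone differed, with a lower effect in LAN-1 (-1.57 ± 0.31, edgeR adjusted p = 0.0118). Its call was lost without Kelly DMSO replicate 1 (0.926), Kelly GSK126 replicate 1 (0.265), LAN-1 DMSO replicate 1 (0.239) or LAN-1 GSK126 replicate 1 (0.0880). At an unadjusted p under 0.05 there were 619 genes, and DESeq2 called 0 genes with 169 at that level. COL6A1 was the only gene called in both lines at day 2, and no gene was shared in 6 of the 8 leave-outs or with DESeq2, limma-voom or thinned libraries. The exceptions were Kelly DMSO replicate 2 and LAN-1 GSK126 replicate 2, without which 1 gene was shared, and 4 were shared after the correction for GC content and length.

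Effects of GSK126 at day 5 were compared with those at day 2 within each line. In Kelly, PLXNA4, a receptor of axon guidance, had a higher effect at day 5 (1.78 ± 0.20, edgeR adjusted p = 3.37e-11) and IGF2 a lower one (-1.44 ± 0.16, 2.08e-11), and both kept their call whichever library was left out. PLXNA4 also fell with time in DMSO, so its difference lies partly in the control libraries. CARTPT, given below, rose with time in DMSO, so the same holds for it. CHRDL1 (5.42 ± 1.27 as fitted, with few counts) and WASF3 (2.47 ± 0.60) had a higher effect at day 5, and KLF15 (-2.11 ± 0.51) and CARTPT, a neuropeptide gene (-1.98 ± 0.45), a lower one. Their adjusted p ran from 0.00981 to 0.0240, and their highest was 0.272 for CHRDL1 and 0.232 for KLF15 without DMSO day 2 replicate 2, and 0.249 for WASF3 and 0.157 for CARTPT without DMSO day 5 replicate 1. The adrenergic list had a lower effect at day 5, with 7 of 26 members called lower and 0 higher, and 9 lower and 1 higher adjusted over the list alone (median -0.09, camera adjusted p = 1.10e-07, and 0.0414 with an estimated correlation). In all, 45 genes differed (24 higher, 21 lower), and DESeq2 called 14. The count was 22 without DMSO day 5 replicate 1, 24 without GSK126 day 2 replicate 1, 27 without GSK126 day 2 replicate 2 and 26 without GSK126 day 5 replicate 2. The days shared 13 genes called higher, where independent lists would share 0.659 (Fisher's exact p = 2.80e-15 across genes), among them COL1A1, NOTCH2 and AGRN, of which COL1A1 alone kept its day 2 call in every leave-out. The 13 fell to 2 and 6 without DMSO day 2 replicates 1 and 2, 5 and 6 without GSK126 day 2 replicates 1 and 2, 8 without DMSO day 5 replicate 2, 2 with DESeq2, 5 with thinned libraries and 6 at an adjusted p under 0.01. CEP44 was called lower on both days, but no gene was without DMSO day 2 replicate 1 or either GSK126 day 2 replicate, or with DESeq2.

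In LAN-1, PLXNA4 also had a higher effect at day 5 (2.21 ± 0.38, edgeR adjusted p = 9.04e-05), but not without DMSO day 2 replicate 1 (0.0615). In this line too PLXNA4 fell with time in DMSO. NHSL2 (2.40 ± 0.64, 0.0491) had a higher effect, and COQ3 (-2.52 ± 0.65, 0.0387), ZNF300 (-1.15 ± 0.28, 0.0217) and DCK, a nucleoside kinase (-1.10 ± 0.26, 0.0143), a lower one. The highest adjusted p was 0.173 for DCK without DMSO day 2 replicate 1. It was 0.376 for NHSL2, 0.227 for COQ3 and 0.186 for ZNF300 without GSK126 day 2 replicate 1. In all, 64 genes differed (51 higher, 13 lower), and DESeq2 called 35. The count was 28 without DMSO day 2 replicate 1, 36 without DMSO day 2 replicate 2, 37 without DMSO day 5 replicate 1, 24 without DMSO day 5 replicate 2, 24 without GSK126 day 2 replicate 1 and 223 without GSK126 day 5 replicate 1. After the correction for GC content and length 18 genes were called. The days shared 10 genes called higher, among them COL6A1, where independent lists would share 0.442 (Fisher's exact p = 2.49e-12 across genes), and 0 called lower. The 10 fell to 2 and 3 without DMSO day 2 replicates 1 and 2, 4 without GSK126 day 2 replicate 1, 6 without DMSO day 5 replicate 1, 5 with thinned libraries, 4 at an adjusted p under 0.01 and 1 with DESeq2 (Fisher's exact p = 0.0518), and 22 were shared after the correction for GC content and length.

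On average over both lines and days, GSK126 lowered EZH2 itself and CEP44 and raised NGFR. EZH2 fell by a log2 of -0.27 ± 0.06 (edgeR adjusted p = 0.00155, n = 8 per treatment) and CEP44 by -0.54 ± 0.06 (8.09e-14). NGFR rose (1.31 ± 0.26, 2.17e-04). CDKN1A was called higher (3.39e-04), but it had few counts in LAN-1 with DMSO, did not pass in Kelly on either day and differed between lines at day 5, so no mean fold is given. EZH2 lies at chromosome 7:148504349-148581413. INSR, YBX3 and KIAA1804 were called higher too (1.72e-09, 1.20e-09 and 1.08e-04), but their effects differed between lines at day 5 and none was called in LAN-1, so no mean fold is given. Other large fitted rises, which depend on few counts, were those of MB21D2 (3.30, 2.22e-04), STARD8 (3.15, 0.00406) and SOX13 (2.83, 1.18e-04). PSMC3IP (-0.66 ± 0.18, 0.0116), LINC00682 (-0.60 ± 0.16, 0.00696), NFKB2, a subunit of NF-kappaB (-0.53 ± 0.17, 0.0322), CENPC, a centromere protein gene (-0.50 ± 0.11, 7.33e-04), and SURF2 (-0.50 ± 0.14, 0.0148) fell. The calls of STARD8 (1 without LAN-1 GSK126 day 2 replicate 2), PSMC3IP (0.0911) and SURF2 (0.0976, both without Kelly DMSO day 5 replicate 2) and NFKB2 (0.0950 without Kelly GSK126 day 2 replicate 1) were lost in some leave-outs.

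In the same mean comparison CASZ1, a neural crest zinc finger gene, was higher (0.34 ± 0.10, edgeR adjusted p = 0.0181), and so was CLU (0.23 ± 0.08, 0.0398). They lost their call without 8 and 12 of the 16 libraries, up to 0.112 (CASZ1, without LAN-1 DMSO day 2 replicate 1) and 0.326 (CLU, without Kelly GSK126 day 5 replicate 1). MYCN (-0.10 ± 0.04, 0.122) and EZH1 (-0.26 ± 0.12, 0.212) did not pass, and RUNX3 had no counts in LAN-1. In all, 768 genes were called, 512 higher and 256 lower, and DESeq2 called 272.

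Time in culture without the drug changed fewer genes than GSK126 did at day 5, and RET and PLXNA4 were among those that fell in Kelly. From day 2 to day 5 in DMSO, RET fell from 193.9 ± 9.95 to 91.8 ± 0.867 CPM (-1.08 ± 0.13, edgeR adjusted p = 2.82e-10, n = 2 per group) and PLXNA4 fell (-1.10 ± 0.16, 1.79e-06). ISLR2 (-1.29 ± 0.25, 6.99e-04) and SMAD6, an inhibitor of BMP signalling (-0.99 ± 0.23, 0.0105), fell, and CDH13, a cadherin (1.83 ± 0.45, 0.0298), IRAK3 (1.702 ± 0.38, 0.00716), ARID5B (1.45 ± 0.34, 0.0146) and CARTPT (1.39 ± 0.31, 0.00670) rose. RET and PLXNA4 alone kept their call in every leave-out. The highest adjusted p was 0.166 for ISLR2, 0.596 for CDH13, 0.166 for IRAK3, 0.327 for ARID5B and 0.526 for CARTPT without DMSO day 5 replicate 1, and 0.298 for SMAD6 without DMSO day 2 replicate 2. In all, 52 genes were called (28 higher, 24 lower), with 15 by DESeq2, and 10 without DMSO day 5 replicate 1.

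In LAN-1, KCTD12, a subunit of GABA-B receptors, fell with time from 1013 ± 56.2 to 422.3 ± 51.6 CPM (-1.27 ± 0.10, edgeR adjusted p = 2.88e-17). ASNS, the asparagine synthetase (0.88 ± 0.15, 2.10e-05), and DACH1, a transcription factor (1.32 ± 0.24, 2.41e-04), rose, and these 3 genes kept their call in every leave-out. PLXNA4 (-1.62 ± 0.31, 5.16e-04) and SMAD6 (-1.25 ± 0.19, 3.72e-06) fell. TOX3 (1.00 ± 0.25, 0.0284) and SLC7A11, a cystine transporter (0.76 ± 0.15, 0.00113), rose. The highest adjusted p was 0.0559 for SMAD6 and 0.757 for SLC7A11 without DMSO day 5 replicate 1, 0.697 for TOX3 without DMSO day 5 replicate 2, and 0.586 for PLXNA4 without DMSO day 2 replicate 1. In all, 52 genes were called (14 higher, 38 lower), with 22 by DESeq2. The count was 23 without DMSO day 2 replicate 1, 27 without DMSO day 2 replicate 2, 21 without DMSO day 5 replicate 1 and 32 without DMSO day 5 replicate 2.

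The make-up of the libraries was compared between treatments within line and day, 8 libraries against 8, by an exact stratified permutation of 1296 regroupings with a smallest possible p of 0.00154. Replication-dependent histone genes held 1.27% (SD 0.0825) of the counts in DMSO and 1.21% (SD 0.114) with GSK126, a difference of -0.0651 points (exact p = 0.139, adjusted over 4 measures 0.278). The difference was -0.0401 without Kelly DMSO day 2 replicate 2 and -0.0410 without LAN-1 GSK126 day 5 replicate 1. Its exact p was 0.0432 without Kelly DMSO day 2 replicate 1 (adjusted 0.0509) and 0.0417 without LAN-1 GSK126 day 5 replicate 2 (adjusted 0.0833). The total count differed by -120890 (exact p = 0.296), and by -187838 (exact p = 0.0340, adjusted 0.0509) and -53942 without Kelly DMSO day 2 replicates 1 and 2, -79519 without Kelly DMSO day 5 replicate 2, and -188594 and -53185 without LAN-1 GSK126 day 5 replicates 1 and 2. The share of the 10 most abundant genes differed by -0.0718 points (exact p = 0.265), and by -0.116 (exact p = 0.0509) and -0.0277 without Kelly DMSO day 2 replicates 1 and 2. The share of the short RNAs RMRP and RPPH1, a measure added after the data were seen, differed by 0.113 points (exact p = 0.0154, adjusted 0.0617). Without 1 library its adjusted p was under the threshold in 3 cases, with differences of 0.152 points without Kelly DMSO day 2 replicate 2, 0.119 without LAN-1 DMSO day 2 replicate 1 and 0.121 without LAN-1 GSK126 day 2 replicate 1. It was 0.0740 points without Kelly DMSO day 2 replicate 1 (adjusted p = 0.0509). Haematopoietic, epithelial and endothelial markers were not tested as lists, and the summed levels in Kelly at day 5 were 26.1 CPM in DMSO and 22.6 CPM with GSK126 for haematopoietic markers and 7.12 and 6.81 CPM for epithelial markers. The endothelial markers summed to 26.6 CPM in DMSO and 31.6 CPM with GSK126, and KDR among them was called higher there.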

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

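The tests of the genes gained in Kelly, of those gained in LAN-1 among genes with a read, of RGS5, of GC content and of genes higher with time were chosen only after the results were seen, and patterns found and tested on the same data are hypotheses. Of 2301 genes with at most 3 counts over the 4 Kelly DMSO libraries and a read in Kelly with GSK126 at day 5, 53 had at least 10 counts there, with at least 3 in each library. Of these, 27 (50.9%) stood at 5 CPM or more in LAN-1 with DMSO, against 128 of 2248 genes not gained (5.69%, one-sided Fisher's exact p = 5.55e-19 across genes, which are not independent). Without 1 Kelly DMSO library 65 to 80 genes were gained (80 without day 5 replicate 2), and without a Kelly GSK126 library fewer genes reached 10 counts, with 11 of 20 open in LAN-1 without replicate 1 and 10 of 14 without replicate 2, and p stayed at or under 1.09e-07 whichever library of the 2 lines was left out. A part of the gained genes may therefore be genes that another neuroblastoma line expresses, although only 1 other line was available. Open means here only RNA at 5 CPM or more, as chromatin was not measured. The other 26 gained genes stood under that level in LAN-1, 15 of them at 3 or fewer counts. LAN-1 RNA mixed into the Kelly libraries did not account for them, as DDX1, amplified in LAN-1, gained 0.0737% of its LAN-1 level (-0.150 to 0.297), where the 27 gained genes open in LAN-1 reached a median of 21.7% (4.12 to 109) and the other 26 a median of 784% of their LAN-1 level (at least 103% each, with LAN-1 levels of 3 or fewer counts over the 4 DMSO libraries set to 3). The rule for gained genes by itself puts the 26 far above the bound of DDX1. The small gain of DDX1 therefore carries this comparison. Depth did not account for the gained genes either, since the reversed rule gave 2 genes.

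The test in LAN-1 could not decide, with 4 gained genes, 1 of them open in Kelly (one-sided Fisher's exact p = 0.105 across all silent genes, many without a read in any library, and 0.270 across those with a read in LAN-1 with GSK126 at day 5). The latter p was 0.00108 without DMSO day 2 replicate 1, 0.00857 without DMSO day 2 replicate 2, 0.00238 without DMSO day 5 replicate 1 and 0.00236 without DMSO day 5 replicate 2, where 8 to 11 genes met the rule. The value of 0.105 met the bound written beforehand for ruling the explanation out, but a minimum of 10 gained genes was set after the value was seen and the case was left open. The gain of RGS5, which stood at 10402 CPM in Kelly, was -0.0216% of its Kelly level (-0.0661 to 0.0228). A rule that was also added later left this case open, because CDKN1A alone among the gained genes was open in Kelly. CDKN1A gained 13.2% of its Kelly level. Of 17 silent genes at 100 CPM or more in Kelly, 0 were gained (median 0%). For CDKN1A these values argue against Kelly RNA mixed into the LAN-1 libraries, and the other gained genes were not covered.

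Many LAN-1 calls at day 5 may come from a trend with GC content between libraries. Across 6431 genes the LAN-1 effect at day 5 correlated with GC content at 0.473, and the Kelly effect at day 5 at -0.131. The median GC content was 39.1% for genes called lower in LAN-1 and 54.3% for those called higher, with 47.9% for all tested genes. After the correction for GC content and length, 30.1% of the genes called lower were still called (43 of 143), 60.5% of those called higher (176 of 291) and 25% of those that differed between days (16 of 64). Genes that lost their call kept part of their change, with median sizes of 0.47 before and 0.26 after correction for lower genes (median SE 0.12 and 0.11), 0.56 and 0.38 for higher genes (0.15 and 0.14) and 0.70 and 0.40 for day differences (0.16 and 0.14), so the calls ended because the changes shrank while the SE hardly did. Without GSK126 replicate 2, which stood apart on GC content, 13, 123 and 41 of these calls were kept. The trend was therefore not the whole cause of the higher calls, and how much of the lower calls and day differences it explains stays open.

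Of 38 genes lower with time in LAN-1, 30 were higher with GSK126 in Kelly (78.9%, 62.7 to 90.5), and of 24 lower with time in Kelly, 22 were higher in LAN-1 (91.7%, 73.0 to 98.97). As the DMSO libraries of the other line are not shared, chance in shared libraries could not produce this. The pattern as first written covered both directions and did not hold for genes that rose with time, of which 4 of 28 from Kelly were lower in LAN-1 (14.3%, 4.03 to 32.7) and 8 of 14 from LAN-1 were lower in Kelly (57.1%, 28.9 to 82.3). In LAN-1 the genes that rose with time in Kelly were thus also mostly higher with GSK126 (median log2 0.40, 5 called higher and 0 lower), so there the pattern is not particular to genes that fell. Genes are not independent, so these intervals are too narrow.

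The 768 calls of the mean comparison were set against 100 splits of the libraries within line and day. Only 1 split gave as many calls, which was the real one, and the highest of the others gave 142. The 100 splits were part of 648 possible ones. Most of the others put libraries with GSK126 and with DMSO into the same group. A drug effect then widens the spread within groups and lowers the number of calls. The numbers of calls in the other splits are therefore no estimate of false calls among the 768.

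Differences of the GSK126 effect between lines and days follow as log2 values from edgeR, and values of genes with few counts are fitted and depend on the prior count. At day 2 the effect in LAN-1 minus that in Kelly was called for AGRN (-1.57).

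At day 5 the effect in LAN-1 was lower than in Kelly for YBX3 (-8.20), SNX10 (-7.39), INSR (-7.35), USP51 (-6.42), FNDC4 (-6.24), KIAA1804 (-5.86), COTL1 (-5.80), CHRDL1 (-5.57) and NOTCH2 (-5.40). Further differences of this sign were those of WASF3 (-3.05), NDN (-2.57), PDGFRA (-2.18), COL3A1 (-1.98), AGRN (-1.66), CNN2 (-1.45), YAP1 (-1.32), KCTD12 (-0.58) and FN1 (-0.52). It was higher in LAN-1 for MKI67 (0.43), MYCN (0.53), MAP1B (0.53), KMT2D (0.64), ALDOA (0.64), SLC3A2 (0.70), PHOX2A (0.72), MCM5 (0.80) and HK2 (0.80). Further differences of this sign were those of CDT1 (0.91), SLC7A5 (1.00), CHGA (1.01), CNTNAP2 (1.11), COL6A1 (1.14), DDC (1.21), DLK1 (1.21), HSPB1 (1.22) and GAL (1.22). Further differences of this sign were those of PFKP (1.53), IGF2 (1.81), NHSL2 (2.11), BAHCC1 (2.46), CDKN1A (3.09), TH (3.25), KCNC4 (3.69) and RNF175 (4.16). TH was nearly absent in LAN-1, with 2 and 0 counts in DMSO at day 5 and 7 and 2 with GSK126, so its value rests on few counts there. Of these 44 calls, 16 were kept whichever of the 8 libraries was left out. For the others the highest adjusted p was 0.0590 for NDN without Kelly DMSO replicate 1. It was 0.432 for PDGFRA, 0.429 for CNN2, 0.402 for MKI67, 0.356 for KMT2D, 0.157 for YAP1, 0.108 for COL3A1, 0.108 for KIAA1804, 0.0782 for FNDC4 and 0.0665 for MCM5 without Kelly DMSO replicate 2. It was 0.163 for USP51 without Kelly GSK126 replicate 1. It was 0.383 for SLC3A2 and 0.110 for COTL1 without Kelly GSK126 replicate 2. It was 0.521 for FN1, 0.335 for RNF175, 0.318 for KCNC4, 0.209 for NHSL2, 0.208 for DDC, 0.137 for DLK1, 0.111 for PFKP and 0.103 for BAHCC1 without LAN-1 DMSO replicate 1. It was 0.215 for KCTD12, 0.213 for CDKN1A and 0.0642 for MAP1B without LAN-1 DMSO replicate 2. It was 0.391 for TH without LAN-1 GSK126 replicate 1. It was 0.207 for CDT1, 0.199 for PHOX2A and 0.0566 for GAL without LAN-1 GSK126 replicate 2.

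In Kelly the effect at day 5 was lower than at day 2 for KLF15 (-2.11), CARTPT (-1.98), IGF2 (-1.44), DBH (-1.17), DLK1 (-1.14), TH (-1.02) and GAL (-0.91). Further differences of this sign were those of SLC7A5 (-0.90), HK2 (-0.83), INSM2 (-0.82), DDC (-0.71), TFAP2B (-0.57), CNTNAP2 (-0.54) and CHGA (-0.50). It was higher at day 5 for FN1 (0.69), RET (0.96), KCTD12 (1.00), PLK2 (1.46), PLXNA4 (1.78), WASF3 (2.47) and CHRDL1 (5.42). Of these 21 calls, 10 were kept whichever of the 8 libraries was left out. For the others the highest adjusted p was 0.105 for HK2 without DMSO day 2 replicate 1. It was 0.279 for FN1, 0.272 for CHRDL1 and 0.232 for KLF15 without DMSO day 2 replicate 2. It was 0.378 for GAL, 0.360 for CNTNAP2, 0.249 for WASF3 and 0.157 for CARTPT without DMSO day 5 replicate 1. It was 0.630 for TFAP2B, 0.197 for DDC and 0.0961 for CHGA without GSK126 day 5 replicate 2.

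In LAN-1 the effect at day 5 was below that at day 2 for COQ3 (-2.52), ZNF300 (-1.15) and DCK (-1.10). The day 5 effect was higher for MAP1B (0.49), FN1 (0.58), MKI67 (0.68), CREBBP (0.68), KMT2D (0.97), KCNQ1OT1 (1.26), PLXNA4 (2.21) and NHSL2 (2.40). Of these 11 calls, 3 were kept whichever of the 8 libraries was left out. For the others the highest adjusted p was 0.173 for DCK and 0.0615 for PLXNA4 without DMSO day 2 replicate 1. It was 0.341 for FN1, 0.272 for MAP1B and 0.188 for KCNQ1OT1 without DMSO day 5 replicate 2. It was 0.376 for NHSL2, 0.227 for COQ3 and 0.186 for ZNF300 without GSK126 day 2 replicate 1.

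Lists were also called by camera for these differences, given as the median difference, the camera adjusted p and the adjusted p with an estimated correlation. Lists that differed between lines at day 2 (LAN-1 minus Kelly) were neuronal differentiation (0.09, 0.0336, 0.158), mesenchymal identity (-0.35, 0.00553, 0.128), mitosis (0.12, 0.0254, 0.319), sterol synthesis (0.24, 8.29e-07, 0.151), integrated stress (0.07, 0.0371, 0.273) and heat shock (0.08, 0.0367, 0.376). Lists that differed between lines at day 5 were neuronal differentiation (0.17, 3.13e-04, 0.0414), adrenergic identity (0.37, 3.58e-05, 0.0899), mesenchymal identity (-0.29, 6.72e-04, 0.107), G1/S (0.16, 0.00754, 0.285), sterol synthesis (0.21, 3.44e-04, 0.248), integrated stress (0.14, 0.00608, 0.162), hypoxia (0.37, 6.99e-05, 0.158) and imprinted genes (0.27, 0.0379, 0.251). Lists that differed between days in Kelly (day 5 minus day 2) were adrenergic identity (-0.09, 1.10e-07, 0.0414), mesenchymal identity (0.32, 0.00715, 0.158), G1/S (-0.08, 0.0380, 0.393), MYC targets (-0.17, 3.02e-04, 0.107), integrated stress (-0.23, 0.00592, 0.162), hypoxia (-0.32, 1.25e-06, 0.107), retinoid response (0.15, 0.0371, 0.279) and imprinted genes (0.01, 0.0146, 0.166). Lists that differed between days in LAN-1 were neuronal differentiation (0.12, 0.0131, 0.108), mesenchymal identity (0.32, 0.0209, 0.171), mitosis (-0.14, 0.0254, 0.319), retinoid response (0.54, 0.00477, 0.158), imprinted genes (0.17, 0.0433, 0.255) and H3K27 and H3K36 modifiers (0.23, 8.29e-06, 0.0899). Many of these calls were lost when 1 of the 16 libraries was left out, given as the number of such libraries and the highest camera adjusted p. For differences between lines at day 2 these were integrated stress (5, 0.449 without Kelly DMSO day 2 replicate 2), mitosis (4, 0.524 without LAN-1 DMSO day 2 replicate 1), neuronal differentiation (4, 0.271 without Kelly DMSO day 2 replicate 2), heat shock (4, 0.184 without LAN-1 DMSO day 2 replicate 1) and mesenchymal identity (1, 0.0621 without Kelly GSK126 day 2 replicate 1). For differences between lines at day 5 these were imprinted genes (14, 0.305 without LAN-1 GSK126 day 5 replicate 1) and G1/S (1, 0.0965 without LAN-1 DMSO day 5 replicate 1). For differences between days in Kelly these were retinoid response (14, 0.313 without Kelly DMSO day 2 replicate 2), G1/S (4, 0.217 without Kelly DMSO day 5 replicate 2), imprinted genes (3, 0.0841 without Kelly DMSO day 2 replicate 1), mesenchymal identity (3, 0.157 without Kelly DMSO day 2 replicate 2) and integrated stress (1, 0.05003 without Kelly GSK126 day 5 replicate 2). For differences between days in LAN-1 these were imprinted genes (6, 0.305 without LAN-1 GSK126 day 5 replicate 1), mesenchymal identity (3, 0.104 without LAN-1 GSK126 day 5 replicate 1), mitosis (3, 0.356 without LAN-1 DMSO day 2 replicate 1) and neuronal differentiation (1, 0.0657 without LAN-1 DMSO day 5 replicate 2). For heat shock between lines at day 2 and imprinted genes between lines at day 5 the mean had the opposite sign of the median, and for imprinted genes between days in Kelly the test was downward while the median and the mean were above 0.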

How the results depend on the processing

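Of 361 alternative values for 20 results, 223 stayed the same and 138 changed. A count within a factor of 1.5 of the main value was taken as the same. A difference in library composition was taken as the same if its sign and the outcome of its test held. None of 3106 values of called named genes changed sign, but many lost their call. These genes entered because they were called, and the largest changes between 2 groups also because their libraries did not overlap. A change of sign was therefore unlikely from the start, and its absence is no independent evidence. With DESeq2 91 kept it and 55 lost it, and with glmTreat 59 kept it and 139 lost it. The cause of a change was not tested, and where 1 library was left out or an arm had 1 library, the lone library was assumed to vary like the other groups. Calls by DESeq2 were 2 and 151 in Kelly and 2 and 149 in LAN-1 at days 2 and 5, 272 for the mean, 0 and 63 between lines at days 2 and 5, 14 and 35 between days in Kelly and LAN-1, 15 and 22 with time in DMSO, and 0, 16, 2 and 1 for the calls shared by lines at days 2 and 5 and by days in Kelly and LAN-1. An adjusted p under 0.01 left, in the same order, 7, 309, 10, 202, 380, 0, 125, 25, 23, 27, 33, 0, 29, 7 and 4. A log2 threshold of 0.5 by glmTreat left 2, 138, 0 (131 at unadjusted p under 0.05), 33, 47, 0, 61, 6, 4, 1 and 6. Thinned libraries gave 5 and 366 in Kelly at days 2 and 5, 10 in LAN-1 at day 2, 0 between lines at day 2, and 0, 45, 5 and 5 shared calls. The GC correction gave 36 and 37 at day 2 in Kelly and LAN-1, 2 between lines at day 2, 71 and 18 between days, 111 and 91 with time, and 4 (lines, day 2), 23 (Kelly) and 23 (LAN-1) shared calls. The contrast alone gave 39 (31 higher, 8 lower) and 261 in LAN-1 at days 2 and 5, 81 with time in LAN-1 and 2 shared at day 2, and the line alone gave 0 shared. Between lines at day 2, no filter gave 2 and limma-voom 0, and for the calls shared there DESeq2 size factors and limma-voom gave 0. Of 76 list calls, 9 were called with an estimated correlation, and fry called 49, of which 44 were among the 76.

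Leaving out 1 library gave 2 to 11 calls in Kelly and 3 to 14 in LAN-1 at day 2, 239 to 355 and 139 to 735 at day 5, 577 to 960 for the mean, 0 to 2 and 117 to 479 between lines, 22 to 46 and 24 to 223 between days, and 10 to 40 and 21 to 32 with time. Shared calls ran from 0 to 1 and 30 to 66 between lines and from 2 to 13 and 2 to 9 between days, and list calls from 57 to 74. The difference in total count ran from -188600 to -53190, that of the 10 most abundant genes from -0.116 to -0.0277 points, of histone genes from -0.0902 to -0.0401 and of RMRP and RPPH1 from 0.0740 to 0.152. The share of LAN-1 calls at day 5 that were higher was 67.1%, and 50.7% without GSK126 replicate 1 or 86.9% without replicate 2. After the GC correction 57 of the 76 list calls were kept, and 1 list turned direction without a call. With thinned libraries 55 of the 76 were kept. Among named genes, signs reversed only for uncalled genes of Kelly at day 5, EZH1 (0.06812 thinned), RUNX3 (0.01746 after GC correction, 0.1191 without DMSO replicate 1, 0.1293 without GSK126 replicate 1, but -0.1934 without GSK126 replicate 2) and CASZ1 (0.1056 without DMSO replicate 1, 0.04223 without GSK126 replicate 2, but -0.218 without DMSO replicate 2).

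With a replicate block within line, Kelly at day 2 had 8 calls, the calls shared by lines at day 2 were 0 and those shared by days in Kelly 8, and with a replicate block within line and day the lines shared 2. Replicate numbers did not pair across treatments, with correlations between -0.0928 and 0.0733 over 6499 genes in the 4 sets of line and day.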

Other observations

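RET, a receptor tyrosine kinase gene, was called higher in both lines at day 5. It rose by a log2 of 1.25 ± 0.12 in Kelly and 0.85 ± 0.14 in LAN-1 (edgeR adjusted p = 1.24e-14 and 5.89e-06), and both calls were kept whichever library was left out. RET had fallen with time in Kelly without the drug (-1.08 ± 0.13). RET was singled out here after its values were seen.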
